A study of Mus musculus with 24 samples.

How the data were processed

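The samples were 24 total RNA preparations of 3T3-L1 cells, a mouse fibroblast line that can be turned into adipocytes in culture. Per the labels, RNA was extracted with Trizol, cleaned on RNeasy columns, amplified to biotinylated cRNA and hybridised to Illumina beadchips. The labels give 8 time points, days 0, 2, 4, 6, 8, 10, 14 and 18, with 3 replicates each. Day 0 is labelled undifferentiated, days 2 and 4 differentiating, and days 6 to 18 maturating. The medium named for days 0 to 4 held IBMX, insulin and dexamethasone, and the labels of days 6 to 18 add a maturation medium with insulin, so the medium and the time changed together. Whether day 0 was taken before the inducing medium was added is not given in the sources used here. Whether the replicates are separate cultures is not given in the sources used here, and neither is the chip that each sample was on.

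The authors deposited a table of probe intensity on a linear scale, not background-subtracted and not normalized between arrays, with 25697 probes. Beside each intensity the deposited table holds a detection p-value, the rank of the probe among the array's negative controls, in steps of 1 in 798. A second deposited table holds intensity that the authors had background-subtracted and normalized between arrays by a method not given in the sources used here. Its array medians lay between 9.60 and 9.70 and its lowest values between -13.0 and -10.5, and within each array its values had the rank order of the first table. The labels name GenomeStudio 2011.1 without saying what it was used for. The first table was used, and the second served as an alternative.

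Intensities were background-corrected, quantile normalized and put on the log2 scale with the neqc function of limma 3.58.1 in R 4.3.3, which models the negative controls from the detection p-values and adds an offset of 16. The probe for Ucp1, which was undetected on every array, therefore had day means of 4.34 to 4.51, and differences that start or end there are compressed. Probes with a detection p under 0.05 on at least 3 of the 24 arrays were kept, which left 14160 probes. Of all 25697 probes 23978 carried 1 gene symbol, 0 carried several and 1719 carried none. The Entrez identifier was found in the annotation for 23962 probes, whose symbol was taken from there whether or not it had changed. Each gene was represented by its probe with the highest mean over all arrays, which gave 9558 genes, of which 2644 had more than 1 probe. Gene positions come from the RefSeq annotation of mouse genome build GRCm38.p6.

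Precision depends on signal over background and on the number of arrays. Between 11695 and 12531 probes (45.5% to 48.8%) were detected per array. Mean intensity ranged from 375 to 473 and the highest intensity from 22815 to 28804. The lowest signal among detected probes lay between 4.75 and 4.91 on the log2 scale. Replicates of a day correlated at 0.982 to 0.996 across genes, which are not independent of one another. With 3 arrays per day, the number of arrays limits the precision of every difference.

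One limma fit with a mean per day was made on all 24 arrays, with 16 residual degrees of freedom and 1 spread per gene shared over all days. Genes that changed over the course were called by a moderated F test of the 7 differences from day 0. The 14 comparisons between days were moderated two-sided contrasts of the same fit: each later day with day 0, each day with the one before it, and day 18 with day 6. Calls used a Benjamini-Hochberg adjusted p under 0.05 over the 9558 genes. Where a probe was undetected on all arrays of a day, the change is given as a bound ("at least N-fold"). The bound sets the brighter day's mean against, per array of the dimmer day, the higher of that array's lowest signal among detected probes and the probe's own signal; the adjusted p beside it is that of the fit. No fold is given where both days were below background.

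A total of 30 gene lists was chosen from general knowledge of adipocytes, fibroblasts and the other cell types that a culture could contain, none from these samples. Of their genes 475 were tested, of which 14 are in more than 1 list. Members with no probe that passed the detection filter were not tested, so the counts of a list are out of its tested genes. Lists were tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated for each list. A further 6 lists were made after the data had been seen. The named genes are the 10 with the largest rise and the 10 with the largest fall among called genes whose 3 arrays of one day all lie on one side of the 3 of the other, for day 2 versus day 0, day 18 versus day 0, day 6 versus day 4 and day 18 versus day 6, and the 3 each way for the other comparisons. To these were added up to 4 called members of each list with the largest change, the called members that went the other way, and a fixed set of marker genes. The genes named by size of change make 140 entries of a gene in a comparison, from 89 genes. In 42 of the entries the gene had another probe that passed the filter, and in 0 of those did another probe go in the opposite direction. The tests, the lists, the naming rule and the alternatives were chosen before the data were examined, except where the text says otherwise.

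Replicate numbers were checked for pairing. After removal of the day means, arrays with the same number correlated across genes at a median of 0.53 (0.25 to 0.76) and arrays with different numbers at a median of -0.39 (-0.62 to 0.25), and 24 of 24 arrays correlated best with an array of their own number. The number took up 62.9% of the sum of squares within days. A fit with the replicate number as a block was therefore run beside the main one, and its counts are given where they differ by over 1.5 times. It ended 4 of the 226 list calls: basement membrane for day 4 and for day 10 versus day 0, muscle lineage markers for day 8 versus day 0, and macrophage and leukocyte markers for day 18 versus day 14.

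Other alternatives were quantile normalization without background correction, median centring in place of quantile normalization, the authors' normalized values, no detection filter, a stricter filter (detection p under 0.01 on all 3 arrays of a day), the mean of a gene's probes, array weights, a trended and robust prior, only the arrays of the 2 days compared, and each array left out in turn. A block for the chip was planned and not run, since the chip of each sample is not given in the sources used here. Leaving out day 4 replicate 2 from comparisons that do not use day 4 was added after the data had been seen. The procedure was tested on simulated data, random values with the day 14 mean and the spread of each of the 9558 genes. Into day 18 were put 50 changes of each size. Day 18 versus day 14 recovered 46% of changes of 0.5 on the log2 scale, 98% of changes of 1, and 100% of changes of 2 or 3. There were 13 false calls among 185. The simulated values were independent between genes and arrays and held no shift shared by a replicate number. The real arrays held such a shift, so these rates need not apply to them.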

Results

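Transcript levels were measured on beadchips in 3T3-L1 cells, a mouse fibroblast line that forms fat-storing adipocytes in culture, over a differentiation course of 8 time points. Each of days 0, 2, 4, 6, 8, 10, 14 and 18 had 3 replicates, and day 0 was labelled undifferentiated. The inducing medium held insulin, dexamethasone, which is a synthetic glucocorticoid, and IBMX, which raises cyclic AMP by blocking phosphodiesterases. The labels name it for day 0 too, and whether day 0 was taken before it was added is not given in the sources used here. Expression values are normalized log2 intensities, with means ± SD of n = 3 arrays per day. Differences between days are log2 changes ± SE of the limma fit, also with n = 3 per day. Per array, 45.5% to 48.8% of the 25697 probes were detected, and 9558 genes were tested.

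Over the whole course 7125 of the 9558 genes (74.5%) changed by the moderated F test. Day 0, day 2 and day 4 lay far apart on the first pair of principal components, which took up 49.2% and 29.6% of the variance, while the arrays of days 14 and 18 overlapped. Among 3914 genes that changed and whose day means spanned at least 2-fold, 1339 (34.2%) were highest on day 0 and 752 (19.2%) on day 2. Another 471 (12%) were highest on day 6 and 377 (9.6%) on day 18. The lowest mean fell on day 0 for 1129 genes (28.8%) and on day 4 for 831 (21.2%). Day 4 replicate 2 lay apart from the other day 4 arrays, toward the later days.

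**Figure D1:**
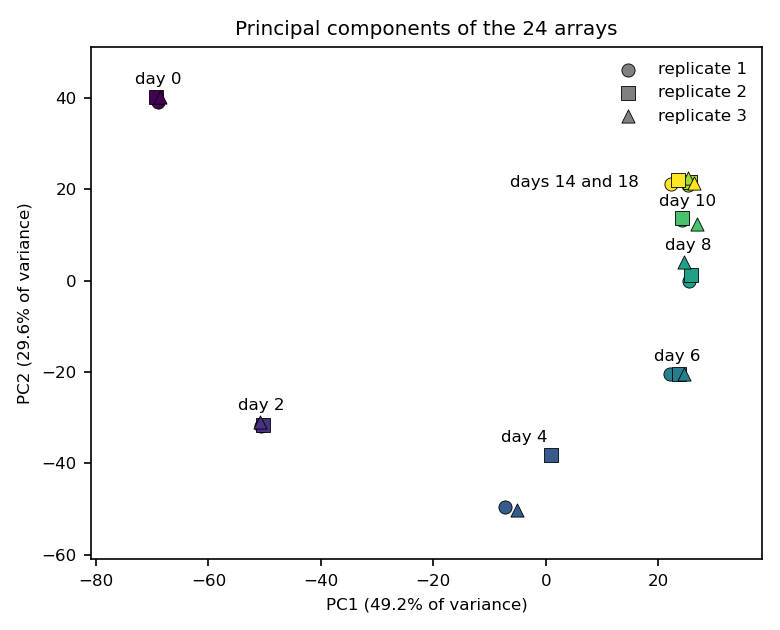
Scores of the 24 arrays on the first principal component (horizontal axis, 49.2% of variance) and the second (vertical axis, 29.6%), with colour for the day and marker shape for the replicate. Days 0, 2, 4 and 6 are separate, days 14 and 18 overlap, and the square of day 4 (replicate 2) lies toward day 6.

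Regulators and markers of fat cells followed distinct courses. Pparg, the nuclear receptor that drives adipogenesis (chromosome 6, 115360879 to 115490404, GRCm38.p6), went from 9.39 ± 0.16 on day 0 to 11.62 ± 0.10 on day 2 and 12.31 ± 0.15 on day 4, and was 12.64 ± 0.09 on day 18. Cebpb, an early factor of the same cascade (chromosome 2, 167688915 to 167690432), was highest on day 2 at 13 ± 0.04, against 11.35 ± 0.06 on day 0. Its later partner Cebpa (chromosome 7, 35119293 to 35121928) was detected on 2 of 3 arrays on day 0 at 5.01 ± 0.26, reached 8.99 ± 0.28 on day 4 and was 7.77 ± 0.24 on day 18. Adipoq, which encodes the hormone adiponectin (chromosome 16, 23146536 to 23157968), was undetected on day 0, and stood at 10.97 ± 0.10 on day 2 and 14.09 ± 0.20 on day 18. Slc2a4, the insulin-regulated glucose transporter (chromosome 11, 69942286 to 69948216), rose later, with 5.41 ± 0.08 on day 2 and 9.80 ± 0.15 on day 6. Lep, which encodes leptin (chromosome 6, 29060221 to 29073876), was undetected on day 0, 6.23 ± 0.09 on day 6 and 7.85 ± 0.05 on day 18. The probe for Fabp4, a fatty acid binding protein (chromosome 3, 10204342 to 10208616), was undetected on days 0 and 2, and reached 6.73 ± 0.34 on day 4 and 7.41 ± 0.19 on day 18.

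Both markers of the starting cells fell and then came part of the way back. Dlk1, which encodes the preadipocyte factor (chromosome 12, 109452485 to 109463336), went from 13.87 ± 0.12 on day 0 to 10.81 ± 0.08 on day 4 and back to 12.17 ± 0.12 on day 18. Col1a1, a chain of type I collagen (chromosome 11, 94936224 to 94953042), went from 12.75 ± 0.23 to 8.76 ± 0.22 on day 4 and 11.25 ± 0.35 on day 18. Ucp1, the uncoupling protein of brown fat, was detected on no array. Cebpd and the proliferation marker Mki67 were not analysed here.

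**Figure D2:**
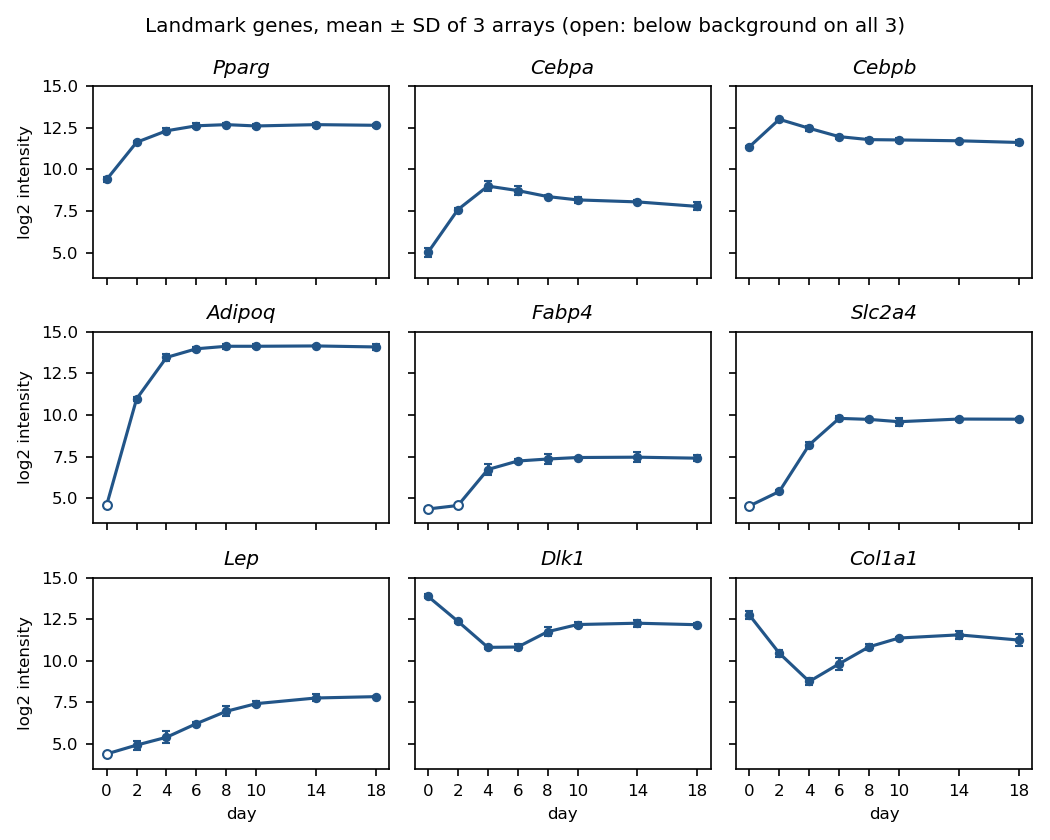
Normalized log2 intensity (vertical axis) of 9 marker genes by day (horizontal axis), as mean ± SD of 3 arrays, with open symbols where the probe was below background on all 3. Adipoq climbs from 4.60 on day 0 to 13.46 on day 4 and levels off, Lep climbs to day 18, and Dlk1 and Col1a1 dip at days 4 to 6.

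Day 2 versus day 0 compares the first day labelled differentiating with the undifferentiated state. The largest rise was that of Pip, which encodes the secreted prolactin-induced protein (chromosome 6, 41847549 to 41852065), at least 125-fold (adjusted p = 4.7e-22). Lcn2, an iron-carrier-binding acute phase protein, rose at least 107-fold, the lipid droplet gene Cidec at least 83.4-fold, Adipoq at least 73.2-fold, and G0s2, an inhibitor of the main triglyceride lipase, at least 38.5-fold. Dgat2, which catalyses the last step of triglyceride synthesis, rose 42.7-fold (log2 5.42 ± 0.08, adjusted p = 1.95e-20), and Hsd11b1, an enzyme that regenerates active glucocorticoid, 46.6-fold (5.54 ± 0.11). The triglyceride synthesis gene Gpat3 and Fam107a rose at least 40.5-fold and 39.7-fold, and Fabp5, a fatty acid binding protein, 24.8-fold. The interferon-stimulated genes Ifit3 (at least 27.9-fold, adjusted p = 3.98e-08), Oasl2 (at least 19.2-fold), Gbp2 (20.2-fold) and Ifi27l2a (15-fold) were among the largest falls. The matrix genes Thbs2 (-4.32 ± 0.26) and Matn4 (-4.07 ± 0.18), the matrix protease Mmp9 (-3.98 ± 0.15), the chemokine Ccl9 (-4.14 ± 0.23), Cdsn (-4.19 ± 0.09) and the membrane glycoprotein Pdpn (-3.84 ± 0.19) fell too.

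Fat cell genes were already moving as a group on day 2. Of 15 adipocyte markers tested 10 rose, 0 fell and 5 did not pass (adjusted p = 1.49e-06), led by Cidec, Adipoq, Agt (4.38 ± 0.12) and Adig (at least 9.91-fold). Among 18 adipogenic transcription factors 10 rose, with Klf5 up by 3.51 ± 0.15, Cebpa by 2.56 ± 0.16, Pparg by 2.22 ± 0.11 and the oxysterol receptor gene Nr1h3 by 2.08 ± 0.09. Zfp467 (-1.10 ± 0.15), Klf4 (-0.81 ± 0.22), Ebf1 (-0.67 ± 0.15) and Zfp423 (-0.44 ± 0.16) of this list fell (adjusted p = 0.00087). Of 19 inhibitors of adipogenesis and preadipocyte markers 14 fell, among them Gata2 (-3.71 ± 0.15), Twist1 (-2.48 ± 0.14), Zfp521 (-2.15 ± 0.10) and Wnt6 (-1.94 ± 0.14), while Foxo1 (1.35 ± 0.14) and Hes1 (0.58 ± 0.13) rose (adjusted p = 0.000146). Fatty acid and triglyceride synthesis genes rose in 13 of 22 cases (adjusted p = 0.000314), including Dgat1 and Agpat2 (both 3.25), and Fads2, Fads1 and Elovl6 fell by 1.57, 1.35 and 0.44. In lipolysis 6 of 10 rose, with Pnpla2, the main triglyceride lipase, up by 4.19 ± 0.07 and Lipe, hormone-sensitive lipase, by 2.97 ± 0.11, and Gnas fell by 0.61 (adjusted p = 0.000274). Of 18 cholesterol synthesis and uptake genes 11 rose, Cyp51 by 1.26 ± 0.13, and Ebp, Fdps and Srebf2 fell by 0.73, 0.36 and 0.26 (adjusted p = 0.0328, and adjusted p = 0.196 with an estimated correlation).

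Of 17 glucocorticoid receptor targets 15 rose and 1 fell (adjusted p = 4.25e-07), among them Lcn2, the receptor co-chaperone gene Fkbp5 (4.12 ± 0.10), Ddit4 (2.91 ± 0.14) and Tsc22d3 (2.44 ± 0.15), and Sgk1 fell by 1.09. Of 15 cAMP-responsive genes 7 rose, with Nfil3 up by 2.81 ± 0.08, Rgs2 by 2.46 ± 0.11 and Dusp1 by 2.22 ± 0.21, while Egr1 (-1.88 ± 0.32), Fos (-0.90 ± 0.32) and Fosb (at least 1.35-fold) fell (adjusted p = 0.0328, and adjusted p = 0.143 with an estimated correlation). The clock list had 4 genes up and 4 down of 12 (adjusted p = 0.996), with Dbp down by 3.03 ± 0.10 and Per1 up by 1.29 ± 0.15. The insulin signalling and glucose uptake list had 6 up and 3 down of 17 (adjusted p = 0.527), with Irs2 up by 1.75 ± 0.27 and Grb14 down at -1.18 ± 0.17.

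Genes of growth and division rose between day 0 and day 2. All 17 ribosome biogenesis genes rose (adjusted p = 2.13e-08), such as Nop56 (2.24 ± 0.21), Rrp12 (2.06 ± 0.09) and Myc (at least 3.74-fold). Of 24 DNA replication genes 20 rose and 0 fell (adjusted p = 2.27e-07), including the cyclin gene Ccne2 (1.87 ± 0.22) and the ribonucleotide reductase subunit Rrm2 (1.68 ± 0.14). Of 16 mitosis genes 13 rose and 0 fell (adjusted p = 2.01e-05), with Top2a, the topoisomerase that untangles sister chromosomes, up by 2.30 ± 0.19. Mitochondrial genes rose as well: 35 of 47 in oxidative phosphorylation (adjusted p = 2.27e-07), 16 of 17 in the citric acid cycle and pyruvate oxidation (adjusted p = 5.87e-07; the pyruvate carboxylase gene Pcx 3.24 ± 0.14) and 12 of 19 in fatty acid oxidation (adjusted p = 0.000326), where Acaa1a fell by 0.33. Branched-chain amino acid catabolism had 10 of 16 up and Pccb down by 0.34 (adjusted p = 0.0384, and adjusted p = 0.0596 with an estimated correlation). Glycolysis and hypoxia had 11 of 18 up, Hk2 by 2.92 ± 0.12, with Ndrg1, Adm, Slc2a1 and Hk1 down (adjusted p = 0.0248, and adjusted p = 0.331 with an estimated correlation). The unfolded protein response list had 10 of 17 up, Xbp1 by 1.21 ± 0.10, with Ddit3 (-1.25 ± 0.16) and Herpud1 (-0.88 ± 0.08) down (adjusted p = 0.0482, and adjusted p = 0.0612 with an estimated correlation).

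Structural genes of the fibroblast and interferon-stimulated genes fell together by day 2. Of 24 genes of the fibrillar and fibroblast matrix 18 fell and 0 rose (adjusted p = 1.49e-06), with Thbs2, Timp3 (-3.34 ± 0.16), Lox (-2.82 ± 0.14) and Lum (-2.82 ± 0.23) at the head. Of 18 actin cytoskeleton and contractile genes 14 fell and 0 rose (adjusted p = 1.07e-05), including the smooth muscle actins Actg2 (-3.64 ± 0.17) and Acta2 (-3.08 ± 0.27) and the tropomyosin gene Tpm1 (-3.22 ± 0.10). Of 18 interferon-stimulated genes 17 fell (adjusted p = 1.11e-07). In the basement membrane list 3 of 14 rose and 7 fell (adjusted p = 0.516), with Col4a1 at 1.32 ± 0.13 and Sparc at -1.31 ± 0.12. The inflammatory and acute phase list divided as well, with 5 of 16 up, led by Lcn2 and Orm1 (4.09 ± 0.13), and 8 down, led by Vcam1 (-2.97 ± 0.16) and Ccl7 (-2.65 ± 0.25) (adjusted p = 0.603). Antioxidant and detoxification genes had 7 of 19 up and 8 down (adjusted p = 0.691), with Sod2 at 1.38 ± 0.11 and Ephx1 at -2.01 ± 0.13. Brown and beige adipocyte markers had 1 of the 7 tested up, Ppargc1b (3.16 ± 0.25) (adjusted p = 0.529).

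In all, 4918 of 9558 genes passed between day 2 and day 0, of which 2385 were higher and 2533 lower on day 2, and 627 and 861 of them by at least 2-fold. The 3 arrays of one day lay wholly on one side of the other day's for 5521 of all 9558 genes, where chance gives 10%. The list calls given without a second p held with an estimated correlation. Adjusted over the list alone, 14 mitosis genes and 21 DNA replication genes rose and the counts of the other lists described were the same. Without background correction 708 genes, in place of 1488, passed and changed at least 2-fold, and the count that passed at any size stayed within 1.5 times.

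Day 4 versus day 2 shows the second step of the stage labelled differentiating. The lipogenic regulator gene Thrsp rose 44.5-fold (5.48 ± 0.16, adjusted p = 1.87e-15), the carboxylesterase gene Ces1d 33.8-fold (5.08 ± 0.09) and Tmem45b at least 25.7-fold. Aldh3a1, an aldehyde dehydrogenase gene, fell by 2.75 ± 0.12, and so did Mgp, which encodes an inhibitor of calcification (-2.70 ± 0.14), and Arsj (-2.40 ± 0.29). Of 15 adipocyte markers 12 rose and 0 fell (adjusted p = 3.87e-10), among them Adig (3.27 ± 0.08), Slc2a4 (2.80 ± 0.12), Adipoq (2.49 ± 0.11) and Fabp4 (at least 3.77-fold). Fatty acid and triglyceride synthesis had 17 of 22 up, including Gpd1, which makes the glycerol backbone (4.00 ± 0.16), and Elovl6 down by 0.90 (adjusted p = 2.74e-10). Lipolysis had 8 of 10 up (adjusted p = 1.02e-05), with Plin1, the lipid droplet coat protein, up by 1.90 ± 0.12. Cholesterol synthesis and uptake had 15 of 18 up, led by Insig1 (2.76 ± 0.12) and Cyp51 (2.31 ± 0.13), and Stard4 down by 0.31 (adjusted p = 2.78e-10).

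Cell division genes turned over between day 2 and day 4. All 16 mitosis genes fell (adjusted p = 1.86e-08), Top2a by 1.68 ± 0.19 and Nusap1 by 1.30 ± 0.17, and 21 of 24 DNA replication genes fell (adjusted p = 4.92e-10), Mcm5 by 1.43 ± 0.09. Ribosome biogenesis had 14 of 17 down (adjusted p = 1.42e-05), Ncl by 1.15 ± 0.20. Matrix genes fell further, 17 of 24 (adjusted p = 7.38e-08), among them Timp2 (-1.89 ± 0.11), Timp1 (-1.84 ± 0.14) and Lox (-1.72 ± 0.14), and so did 13 of 18 actin genes (adjusted p = 0.000266), with Acta2 at -1.69 ± 0.27. In the basement membrane list 9 of 14 fell, Nid2 by 1.49 ± 0.11, and Col15a1 rose by 1.00 ± 0.15 (adjusted p = 0.000349). Inhibitors of adipogenesis and preadipocyte markers had 11 of 19 down, led by Pdgfra (-1.8 ± 0.10) and Zfp521 (-1.62 ± 0.10), with Ddit3 (2.14 ± 0.16) and Foxo1 (0.46 ± 0.14) up (adjusted p = 0.0108).

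Mitochondrial lists rose again from day 2 to day 4. Oxidative phosphorylation had 32 of 47 up (adjusted p = 1.21e-10), fatty acid oxidation 17 of 19 (adjusted p = 1.21e-10; Crat 2.24 ± 0.15) and branched-chain amino acid catabolism 11 of 16 (adjusted p = 7.38e-08; Bcat2 2.31 ± 0.15), none with a member that fell. The citric acid cycle list had 14 of 17 up and the isocitrate dehydrogenase genes Idh2 and Idh1 down by 1.04 and 0.33 (adjusted p = 2.63e-05). The unfolded protein response list had 8 of 17 up and 0 down (adjusted p = 0.000493), with the stress genes Trib3 (2.52 ± 0.22) and Ddit3 at the head. Brown and beige markers had 5 of 7 up (adjusted p = 0.00334, and adjusted p = 0.0655 with an estimated correlation), with Elovl3, a fatty acid elongase gene, at least 5.68-fold higher and Cox8b at least 7.76-fold. Cox8b was at 9.78 on day 4 replicate 2 and at 6.66 and 6.88 on the other day 4 arrays, and without replicate 2 it was at least 3.87-fold higher (adjusted p = 3.98e-11). Antioxidant genes had 10 of 19 up, Gsta3 by 2.45 ± 0.11, and Txnip, Ephx1 and Gpx1 down (adjusted p = 0.00563, and adjusted p = 0.0878 with an estimated correlation).

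Between day 4 and day 2, 3958 genes passed, 1789 higher and 2169 lower. Adjusted over the list alone, 3 inhibitors of adipogenesis, 33 oxidative phosphorylation genes and 18 fatty acid oxidation genes rose, and the counts of the other lists described were the same. Without day 4 replicate 2 it was 3620, of which 3451 passed in both fits with 0 of them in opposite directions. The rise of Lep by 0.48 ± 0.16 (adjusted p = 0.0248) did not pass without that array, at 0.29 ± 0.16 (adjusted p = 0.178). Against day 0, day 4 had 5745 genes passed, 2763 higher and 2982 lower (5494 without replicate 2). The largest changes from day 0 were in Adipoq (at least 410-fold), Cidec (at least 308-fold) and Dgat2 (183-fold) upward, and in Matn4 (-5.39 ± 0.18), Pdpn (-5.36 ± 0.19) and Prokr1 (-5.00 ± 0.19), a prokineticin receptor gene, downward. All 24 matrix genes were lower on day 4 than on day 0 (adjusted p = 1.43e-09).

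Day 6 versus day 4 spans the change from the stage labelled differentiating to the one labelled maturating. The apolipoprotein gene Apoc1 (chromosome 7, 19689480 to 19692659) rose 16-fold (4.00 ± 0.57, adjusted p = 1.49e-05) and the ubiquitin-like Ubd 14.7-fold (3.88 ± 0.50). Selenbp1 rose 11.1-fold (3.48 ± 0.23), Pdlim4 10.1-fold (3.33 ± 0.26), Cyb561 9.98-fold (3.32 ± 0.16), Ghrh 9.17-fold (3.20 ± 0.24) and Sult1a1, a sulfotransferase gene, 6.37-fold (2.67 ± 0.11). Cox8b rose by 3.05 ± 0.47, Mettl7b by 2.77 ± 0.29 and Rarres2, which encodes the adipokine chemerin, by 2.65 ± 0.41. Pip fell at least 49.8-fold (adjusted p = 1.19e-20), and Lcn2 fell by 4.03 ± 0.17 and Retnla, a resistin-like gene, too (-3.85 ± 0.08). Ang4 (-2.90 ± 0.11), Inhba (-2.27 ± 0.29), which encodes an activin subunit, the chemokine gene Cxcl13 (-2.20 ± 0.13) and Emb (-2.18 ± 0.12) fell too, along with Top2a, Nusap1 and Mcm5.

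Day 4 replicate 2 stood apart from its day in the genes that rose most. Apoc1 was at 12 on it and at 8.25 and 8.31 on the other day 4 arrays, Ubd at 9.60 against 6.50 and 6.33, and Rarres2 at 11.84 against 9.24 and 9.12. Car3, a carbonic anhydrase gene of fat and muscle, was at 8.23 on that array, above its day 6 values of 6.42 to 6.91. Lcn2 and Pip did not differ this way, with Pip at 10.43 on that array and 10.70 and 10.41 on the others. Without it the rises were larger, at 5.24 ± 0.09 for Apoc1, 4.94 ± 0.13 for Ubd, 4.06 ± 0.12 for Cox8b, 3.53 ± 0.11 for Rarres2 and 3.37 ± 0.11 for the glycerol channel gene Aqp7 (2.62 ± 0.35 with it).

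**Figure D3:**
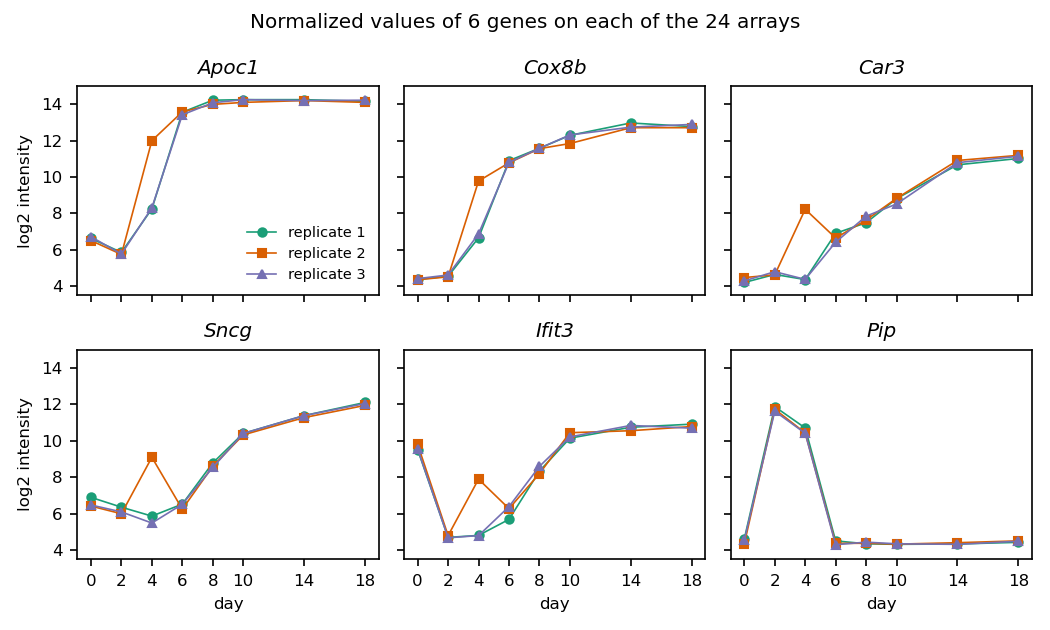
Normalized log2 intensity (vertical axis) of 6 genes by day (horizontal axis), with 1 line and marker per replicate number. Day 4 replicate 2 is at 12 for Apoc1, 8.23 for Car3, 9.09 for Sncg and 7.89 for Ifit3, above both other day 4 arrays, and lies with them for Pip.

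Cell division genes kept falling from day 4 to day 6. Of 16 mitosis genes 14 fell and 0 rose (adjusted p = 5.44e-14), including Top2a (-2.36 ± 0.19), Nusap1 (-2.15 ± 0.17) and Birc5 (-1.97 ± 0.12). DNA replication had 19 of 24 down (adjusted p = 3.64e-14), with the helicase subunit Mcm5 at -2.17 ± 0.09 and thymidine kinase Tk1 at -1.77 ± 0.13, and ribosome biogenesis 14 of 17 down (adjusted p = 6.73e-08), with Nop56 at -1.26 ± 0.21. Adipocyte markers had 9 of 15 up (adjusted p = 3e-05), with Aqp7 (2.62 ± 0.35) and Slc2a4 (1.59 ± 0.12) at the head. Fatty acid and triglyceride synthesis had 9 of 22 up and Agpat2 down by 0.63 (adjusted p = 6.9e-05); the desaturase genes Fads2 and Fads1, which had fallen by day 2, rose by 2.44 ± 0.18 and 1.48 ± 0.16. Cholesterol synthesis and uptake had 11 of 18 up (adjusted p = 6.9e-05; Tm7sf2 1.77 ± 0.22), fatty acid oxidation 12 of 19 (adjusted p = 3.27e-05; Acaa2 1.02 ± 0.10) and branched-chain amino acid catabolism 10 of 16 (adjusted p = 3e-05; Dbt 1.41 ± 0.18). The clock list had 6 of 12 up and 0 down (adjusted p = 0.00191), with Dbp at 0.86 ± 0.10 and Cry2 at 0.85 ± 0.18.

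Interferon-stimulated genes had 9 of 18 up, Gbp2 by 2.58 ± 0.28 and Gbp3 by 1.28 ± 0.19 (adjusted p = 0.00155, and adjusted p = 0.262 with an estimated correlation). Without day 4 replicate 2, where Ifit3 stood at 7.89 against 4.80 and 4.79, 11 of the 18 rose (adjusted p = 1.35e-06, and adjusted p = 0.0144 with an estimated correlation). Actin genes had 7 of 18 up, Acta2 by 2.33 ± 0.27 (adjusted p = 0.0183, and adjusted p = 0.221 with an estimated correlation), and 8 without that array (adjusted p = 0.00213 and 0.0458). Matrix genes divided, with 8 of 24 up, led by Thbs2 (1.40 ± 0.26) and Lox (1.17 ± 0.14), and Tnc, Mmp2 and Loxl1 down (adjusted p = 0.255), while without that array 9 rose (adjusted p = 0.0232, and adjusted p = 0.109 with an estimated correlation). Glycolysis and hypoxia had 10 of 18 up, Egln3 by 1.66 ± 0.21 (adjusted p = 6.9e-05, and adjusted p = 0.12 with an estimated correlation). Antioxidant genes had 10 of 19 up, Ephx1 by 1.80 ± 0.13, and Nqo1 (-1.16 ± 0.13) and Gsta3 (-0.36 ± 0.11) down (adjusted p = 0.00117, and adjusted p = 0.0686 with an estimated correlation). Adipogenic transcription factors had 5 of 18 up, among them Klf15 (1.53 ± 0.27), and 6 down, led by Klf5 (-1.97 ± 0.15) and Egr2 (-1.39 ± 0.25) (adjusted p = 0.801). Oxidative phosphorylation had 5 of 47 up and 5 down (adjusted p = 0.981).

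Between day 6 and day 4, 2805 genes passed, 1463 higher and 1342 lower. Adjusted over the list alone, 14 cholesterol genes rose and 1 fell, 21 DNA replication and 16 ribosome biogenesis genes fell, 8 actin genes rose and 1 fell, and the counts of the other lists described differed by at most 1. Without day 4 replicate 2 the count was 2655, of which 2451 passed in both fits with 0 in opposite directions. The rise of Pparg by 0.30 ± 0.11 (adjusted p = 0.0392) did not pass without it, at 0.23 ± 0.12 (adjusted p = 0.17). Against day 0, 5808 genes passed on day 6, 2641 higher and 3167 lower, with Cidec at least 505-fold, Adipoq at least 589-fold and Thrsp at least 263-fold higher, and Mmp3, which encodes the matrix protease stromelysin, at least 22.4-fold lower, Matn4 at -4.83 ± 0.18 and Pdpn at -4.48 ± 0.19.

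Steps between later days were smaller. From day 6 to day 8 glucocorticoid targets fell: Fkbp5 by 2.77 ± 0.10 (adjusted p = 8.28e-13) and 11 of 17 listed targets in all (adjusted p = 1.04e-11), including Errfi1 (-1.47 ± 0.12) and Cdkn1a (-1.06 ± 0.10). Fam107a fell by 2.66 ± 0.11 and Cyp2e1, a cytochrome P450 gene, by 2.45 ± 0.11. The interferon-stimulated gene Ifit3 rose by 2.26 ± 0.49, Sncg, which encodes gamma-synuclein (chromosome 14, 34370274 to 34374669), by 2.21 ± 0.53, and the peroxisomal transporter gene Abcd2 by 2.13 ± 0.43. Interferon-stimulated genes had 10 of 18 up (adjusted p = 1.49e-07, and adjusted p = 0.0624 with an estimated correlation) and matrix genes 11 of 24 (adjusted p = 3.53e-08), Timp3 by 1.5 ± 0.16, with 0 down in either list. Actin genes had 6 of 18 up, Tpm1 by 0.99 ± 0.10 (adjusted p = 0.000298, and adjusted p = 0.0624 with an estimated correlation). Branched-chain amino acid catabolism had 4 of 16 down, Bcat2 by 1.10 ± 0.15 (adjusted p = 0.00453), and the unfolded protein response 5 of 17, Trib3 by 0.72 ± 0.22 (adjusted p = 0.00426). Of 7 muscle lineage markers 3 rose (adjusted p = 0.000759), with Acta1 at 1.28 ± 0.13 and the fast-muscle genes Tnnc2 and Myl1 at least 1.93-fold and 1.63-fold higher.

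From day 8 to day 10 interferon-stimulated genes rose further, 11 of 18 (adjusted p = 1.42e-19), with Ifit3 at 1.90 ± 0.49, Oasl2 at 1.5 ± 0.39 and Gbp3 at 1.28 ± 0.19. Cholesterol synthesis and uptake had 8 of 18 up (adjusted p = 1.04e-13; Sc5d 0.74 ± 0.11), matrix 7 of 24 (adjusted p = 2.84e-10; Timp3 0.70 ± 0.16) and the inflammatory and acute phase list 6 of 16 (adjusted p = 1.13e-06; Cxcl10 0.80 ± 0.12), none with a member that fell. Mlana fell by 1.25 ± 0.15, the clock gene Per1 by 1.22 ± 0.15 and Rgr, an opsin gene, by 1.08 ± 0.10. From day 10 to day 14, 9 of 18 glycolysis and hypoxia genes fell (adjusted p = 3.44e-16), with the oxygen sensor Egln3 at -1.31 ± 0.21, Pfkp at -1.04 ± 0.17 and Pdk1 at -0.91 ± 0.14. The proton channel gene Hvcn1 rose at least 2.85-fold, Slco2b1 by 1.45 ± 0.19 and Plcb2 by 1.31 ± 0.16, while Ghrh fell by 2.08 ± 0.24, Acox2 by 1.49 ± 0.13 and Slc25a34 by 1.48 ± 0.22.

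From day 14 to day 18 mitosis genes rose, 7 of 16 (adjusted p = 1.23e-31), with Birc5 at 1.24 ± 0.12 (adjusted p = 8.27e-06), Prc1 at 1.07 ± 0.10, Top2a at 1.02 ± 0.19 and Cdc20 at 0.99 ± 0.10. DNA replication had 2 of 24 up (adjusted p = 1.88e-08), Tk1 by 1.46 ± 0.13 and Mcm5 by 1.00 ± 0.09. Ghrh, which encodes growth hormone-releasing hormone, rose by 1.51 ± 0.24. The 3 genes that fell were Gsta3 (-0.60 ± 0.11), Pxmp2 (-0.57 ± 0.11) and Pdzk1 (at least 1.37-fold). Mitosis genes were still below day 0 on day 18, as 14 of 16 were lower (adjusted p = 3.95e-06), with Cenpa at -2.08 ± 0.10.

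Genes that passed numbered 1242 between days 6 and 8 (721 higher, 521 lower), 378 between days 8 and 10 (226 and 152), 206 between days 10 and 14 (108 and 98) and 46 between days 14 and 18 (43 and 3). With the replicate number as a block they were 2231, 1016, 573 and 99, and with only the arrays of the days compared 614, 31, 50 and 2. Leaving out single arrays gave 185 to 465 genes for day 10 versus day 8, 112 to 250 for day 14 versus day 10, and 25 to 56 for day 18 versus day 14. Adjusted over the list alone, 13 glucocorticoid targets fell from day 6 to day 8, and 13 interferon-stimulated, 14 matrix, 7 actin, 4 muscle and 1 unfolded protein response genes rose. From day 8 to day 10, 17 interferon-stimulated, 12 cholesterol, 12 matrix and 7 inflammatory genes rose and 1 inflammatory gene fell. From day 10 to day 14, 12 glycolysis and hypoxia genes fell, and from day 14 to day 18, 8 mitosis and 4 DNA replication genes rose.

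**Figure D4:**
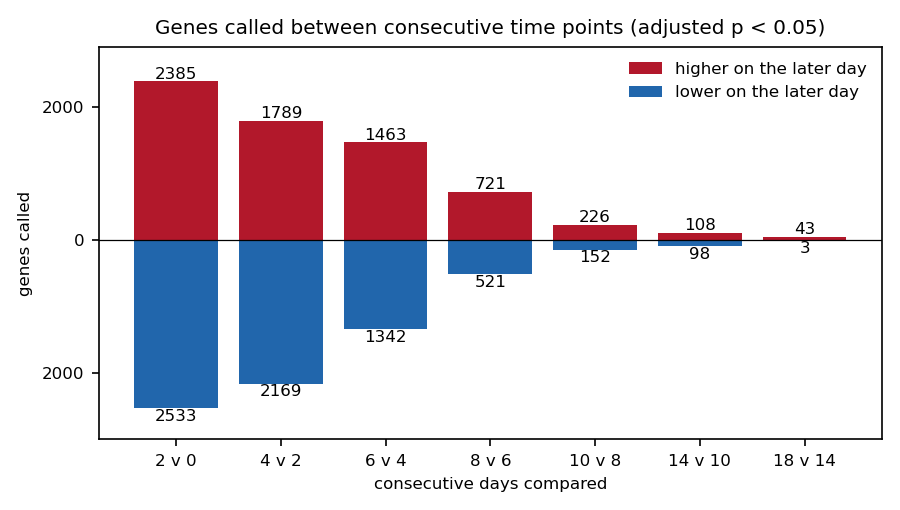
Number of genes that passed between consecutive time points (vertical axis), higher on the later day above the zero line and lower on the later day below it, for each pair of days (horizontal axis). The number falls from 2385 higher and 2533 lower at day 2 versus day 0 to 43 higher and 3 lower at day 18 versus day 14.

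Day 18 versus day 6 shows the change within the stage labelled maturating. The interferon-stimulated genes Ifit3 (chromosome 19, 34583119 to 34588982) and Oasl2 rose by 4.69 ± 0.49 (adjusted p = 2.01e-07) and 3.81 ± 0.39, and so did Psmb9, which encodes a subunit of the immunoproteasome (3.81 ± 0.28), and the complement factor gene Cfb (3.58 ± 0.55). Sncg had the largest rise, 48.5-fold (5.6 ± 0.53, adjusted p = 5.81e-08), and Car3 rose 22.0-fold (4.46 ± 0.60), Abcd2 by 3.83 ± 0.43, the muscle light chain Myl1 at least 11.2-fold, the transporter gene Slco2b1 at least 8.28-fold and Mmp3 at least 8.53-fold. The largest falls were in Pdzk1, a scaffold protein (at least 13.8-fold, adjusted p = 4.84e-16), Fam107a (at least 11.3-fold), the keratin gene Krt14 (at least 8.09-fold), Fkbp5 (-3.22 ± 0.10), Tmem82 (at least 8.13-fold) and Cyp2e1 (at least 5.82-fold). Anxa8 (-2.92 ± 0.12), Rgr (-2.87 ± 0.10), Pkd2l1 (-2.77 ± 0.15) and the apolipoprotein gene Apoc3 (-2.75 ± 0.12) fell too. Sncg, Car3 and Ifit3 were high on day 4 replicate 2, which widens their SE in the shared fit. Without that array the SE were 0.13, 0.12 and 0.15 and the changes were the same. Cfb was high on that array too, at 6.87 against 4.42 and 4.62. On day 6 Cfb was at 4.65 and 4.83 on replicates 1 and 3, below the lowest signal among detected probes, and at 5.72 on replicate 2. On day 18 it was at 7.70, 9.14 and 9.10.

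Interferon-stimulated, matrix and actin genes, which had fallen by day 2, rose over these days, and so did other lists. Of 18 interferon-stimulated genes 17 rose and 0 fell (adjusted p = 2.52e-13), including Isg15 (2.62 ± 0.24). Of 24 matrix genes 17 rose, with Timp3 (2.80 ± 0.16), Thbs2 (2.24 ± 0.26), Lum (2.22 ± 0.23) and Timp1 (2.01 ± 0.14) at the head, and Col6a2 fell by 0.47 (adjusted p = 6.85e-08). Actin genes had 14 of 18 up and 0 down (adjusted p = 2.68e-05), with Tpm1 at 1.63 ± 0.10 and Pdlim7 at 1.62 ± 0.14. The inflammatory and acute phase list had 10 of 16 up, among them Vcam1 (2.34 ± 0.16), Cxcl1 (2.21 ± 0.11) and Cxcl12 (1.92 ± 0.09), and Nfkbia down by 1.09 (adjusted p = 1.4e-05). Cholesterol synthesis and uptake had 14 of 18 up (adjusted p = 6.85e-08), led by Hsd17b7 (1.44 ± 0.12) and Stard4 (1.11 ± 0.10). Muscle lineage markers had 4 of 7 up (adjusted p = 0.00621), with Tnnc2 at least 3.66-fold. Antioxidant genes had 9 of 19 up, Sod3 by 1.70 ± 0.17, and Prdx3 and Gclc down (adjusted p = 0.0218, and adjusted p = 0.17 with an estimated correlation).

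Other lists fell from day 6 to day 18. Of 17 glucocorticoid targets 11 fell and 0 rose (adjusted p = 1.34e-06), Fkbp5, Errfi1 (-2.09 ± 0.12), Cdkn1a (-2 ± 0.10) and Per1 (-1.77 ± 0.15) the most. Branched-chain amino acid catabolism had 9 of 16 down and 0 up (adjusted p = 0.000619), with Bcat2 at -2.12 ± 0.15 and Dbt at -1.32 ± 0.18, the citric acid cycle 8 of 17 (adjusted p = 0.00636; Pdhb -1.02 ± 0.14) and the unfolded protein response 8 of 17 (adjusted p = 0.0245; Trib3 -1.67 ± 0.22). Glycolysis and hypoxia had 11 of 18 down, Ldha by 1.04 ± 0.12, and Adm and Hk1 up at 1.17 ± 0.24 and 0.53 ± 0.16 (adjusted p = 0.00202, and adjusted p = 0.171 with an estimated correlation). Fatty acid oxidation had 7 of 19 down, Acadm by 0.98 ± 0.09, and Acaa2, Cpt1b and Acads up (adjusted p = 0.0299, and adjusted p = 0.0927 with an estimated correlation). Adipogenic transcription factors had 9 of 18 down, led by Klf5 (-2.07 ± 0.15) and Cebpa (-0.96 ± 0.16), and Egr2, Ebf1 and Ebf2 up (adjusted p = 0.0479, and adjusted p = 0.171 with an estimated correlation).

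Several fat cell lists went both ways between days 6 and 18. Adipocyte markers had 5 of 15 up, with Car3, Lep (1.63 ± 0.16), Aqp7 (1.54 ± 0.35) and Cd36 (1.51 ± 0.33), and Agt (-1.8 ± 0.12), Retn (-1.33 ± 0.19) and Cidec (-0.94 ± 0.12) down (adjusted p = 0.247). Fatty acid and triglyceride synthesis had 8 of 22 up, led by Pck1 (2.41 ± 0.51) and Acss2 (1.57 ± 0.12), and 9 down, led by Dgat2 (-1.36 ± 0.08) and Lpin1 (-1.18 ± 0.19) (adjusted p = 0.919). Brown and beige markers had Cidea (3.24 ± 0.29), Cox7a1 (2.17 ± 0.30) and Cox8b (1.96 ± 0.47) up and Elovl3 (at least 2.72-fold) and Ppargc1b (-0.75 ± 0.25) down (adjusted p = 0.572). Among inhibitors of adipogenesis and preadipocyte markers 8 of 19 rose, led by Gata2 (1.65 ± 0.15), Dlk1 (1.34 ± 0.13) and Sox9 (1.07 ± 0.21), and Ddit3, Foxo1 and Wnt6 fell (adjusted p = 0.118). In all 3488 genes passed, 1721 higher and 1767 lower on day 18 (3490 without day 4 replicate 2), of which 455 and 193 changed at least 2-fold. Without background correction 274 genes, in place of 648, passed and changed that much. Adjusted over the list alone, 12 glucocorticoid targets, 8 fatty acid oxidation and 10 lipid synthesis genes fell, 9 of the inhibitors rose and 4 fell, and the other counts were the same.

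Day 18 versus day 0 compares the end of the course with the start. Adipoq was at least 634-fold higher (adjusted p = 1.37e-22), the acute phase gene Hp, which encodes haptoglobin, at least 292-fold, Cidec at least 262-fold, Cox8b, a subunit of cytochrome oxidase found in brown fat and muscle, at least 258-fold and Adig at least 188-fold. The fatty acid receptor gene Ffar2 was at least 131-fold higher, G0s2 at least 134-fold, Thrsp at least 124-fold, Orm1, another acute phase gene, 202-fold (7.66 ± 0.13) and Apoc1 187-fold (7.55 ± 0.57). The largest falls were in the Wnt ligand Wnt6 (10.3-fold, -3.36 ± 0.14, adjusted p = 4.1e-14), the BMP antagonist Grem1 (10.2-fold, -3.35 ± 0.27) and Actg2 (9.38-fold, -3.23 ± 0.17). The calcium channel gene Cacna1g fell by 2.95 ± 0.14, as did the netrin receptor gene Unc5c (-2.87 ± 0.20), Smarca1 (-2.82 ± 0.12), Prokr1 (-2.79 ± 0.19), Acot1 (-2.79 ± 0.12), Spon2 (-2.77 ± 0.08) and Gata2 (-2.73 ± 0.15).

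All 15 adipocyte markers were higher on day 18 (adjusted p = 5.62e-14) and all 18 genes of cholesterol synthesis and uptake (adjusted p = 7.19e-15), led by Insig1 (5 ± 0.12), Tm7sf2 (3.77 ± 0.22), Dhcr7 (3.43 ± 0.11) and Cyp51 (3.33 ± 0.13). Fatty acid and triglyceride synthesis had 20 of 22 higher (adjusted p = 1.01e-14), among them Gpd1 (6.65 ± 0.16), Dgat2 (6.21 ± 0.08) and the desaturase gene Scd1 (5.2 ± 0.14), and lipolysis 8 of 10 (adjusted p = 4.58e-07), with Pnpla2 at 5.15 ± 0.07. Higher too were 41 of 47 oxidative phosphorylation genes (adjusted p = 5.62e-14; Cyc1 1.76 ± 0.11), 18 of 19 in fatty acid oxidation (adjusted p = 3.91e-12; Crat 2.75 ± 0.15), 16 of 17 in the citric acid cycle (adjusted p = 1.11e-08; Pcx 4.41 ± 0.14) and 12 of 16 in branched-chain amino acid catabolism (adjusted p = 6.67e-07; Aldh6a1 3.00 ± 0.32), with 0 lower in each. Antioxidant and detoxification genes had 14 of 19 higher, Gsta3 at least 11.9-fold, and Nqo1 and Ephx1 lower (adjusted p = 1.59e-05), the clock list 9 of 12 higher, Nr1d1 by 1.66 ± 0.15 (adjusted p = 0.00417), and the unfolded protein response 9 of 17 higher, Chac1 by 2.06 ± 0.09, with Calr and Hsp90b1 lower (adjusted p = 0.00445).

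Lower on day 18 were 22 of 24 DNA replication genes (adjusted p = 3.95e-06; Mcm5 -1.98 ± 0.09), 19 of 24 matrix genes (adjusted p = 2.62e-05; Tnc -2.07 ± 0.16, Timp1 -2.02 ± 0.14) and 13 of 19 inhibitors of adipogenesis and preadipocyte markers (adjusted p = 0.000786), of which Foxo1 was higher by 0.71 ± 0.14. Actin genes had 11 of 18 lower and Mylk higher (adjusted p = 0.00445, and adjusted p = 0.11 with an estimated correlation), and the basement membrane 9 of 14 lower and Col15a1 higher (adjusted p = 0.00881, and adjusted p = 0.127 with an estimated correlation). Adipogenic transcription factors had 11 of 18 higher, Nr1h3 by 3.56 ± 0.09, and Egr2, Klf5 and Klf4 lower (adjusted p = 0.00445, and adjusted p = 0.0619 with an estimated correlation). Only part of the brown and beige list was tested, without the undetected Ucp1. Of the 7 markers tested 5 were higher, Cox7a1 by 5 ± 0.30 and Cidea at least 18.9-fold (adjusted p = 0.00269, and adjusted p = 0.0582 with an estimated correlation). Glycolysis and hypoxia had 11 of 18 higher, Egln3 by 3.81 ± 0.21, and Slc2a1, Ndrg1 and Hk1 lower (adjusted p = 0.00122, and adjusted p = 0.14 with an estimated correlation). Interferon-stimulated genes had 9 of 18 higher, Psmb9 by 2.66 ± 0.28, and Ifit2 lower (adjusted p = 0.0175, and adjusted p = 0.341 with an estimated correlation). Glucocorticoid targets (9 of 17 higher, 3 lower, adjusted p = 0.173), the inflammatory list (5 of 16 higher, 7 lower, adjusted p = 0.581), cAMP-responsive genes (6 of 15 higher, 5 lower, adjusted p = 0.625), insulin signalling (7 of 17 higher, 4 lower, adjusted p = 0.118) and ribosome biogenesis (3 of 17 higher, 3 lower, adjusted p = 0.94) did not pass as lists.

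**Figure D5:**
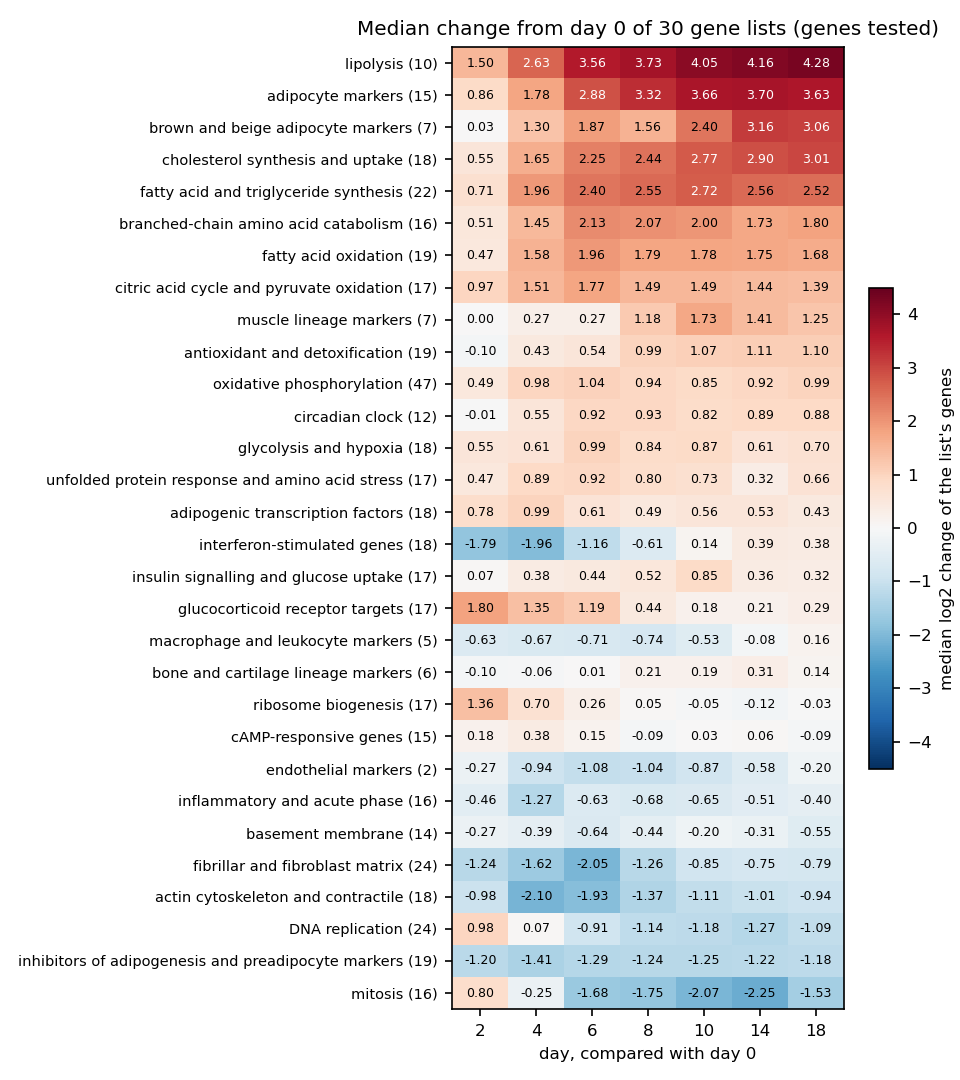
Median log2 change from day 0 (colour and printed value) of the tested genes of each of 30 lists (vertical axis, number of genes tested in brackets), for each later day (horizontal axis). Adipocyte markers are at 3.63 on day 18, matrix genes are lowest on day 6 at -2.05, and interferon-stimulated genes go from -1.96 on day 4 to 0.38 on day 18.

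Markers of other cell types were tested only in part. Of the 30 lists, those of macrophages and leukocytes, endothelium, and bone and cartilage had 5, 2 and 6 genes tested, and none passed as a list between day 18 and day 0 (adjusted p = 0.817, 0.778 and 0.846). In the macrophage list Aif1 was lower by 0.54 ± 0.15, in the endothelial list the receptor gene Flt1 was higher by 0.67 ± 0.20 and Egfl7 lower at -1.07 ± 0.11, and in the bone list Sp7 was at least 1.36-fold and Alpl 0.36 ± 0.15 higher while Sox9 (-0.94 ± 0.21) and Phex (at least 1.42-fold) were lower. Muscle lineage markers had 4 of 7 higher on day 18, Myl1 at least 12-fold, Des by 2.79 ± 0.10, Tnnc2 at least 3.91-fold and Acta1 at least 1.86-fold, and Tnnt3 at least 1.13-fold lower (adjusted p = 0.01, and adjusted p = 0.0508 with an estimated correlation).

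Between day 18 and day 0, 5466 genes passed, 2217 higher and 3249 lower, and 948 and 974 of them by at least 2-fold. Without background correction 994 genes, in place of 1922, passed and changed that much. Adjusted over the list alone, 45 oxidative phosphorylation genes were higher and 2 muscle markers lower, and the counts of the other lists were the same. Against day 0, 5497 genes passed on day 8, 5402 on day 10 and 5362 on day 14. Among the largest changes on those days were Adipoq (at least 651-fold, 653-fold and 662-fold), Cidec (at least 407-fold, 392-fold and 293-fold), Thrsp on day 8 (at least 193-fold), Hp on days 10 and 14 (at least 279-fold and 317-fold), Mmp3 (-3.90 ± 0.32) and Mgp (-3.82 ± 0.14) on day 8, Grem1 (-3.46 ± 0.27), Aqp1 (-3.32 ± 0.15) and Prl2c4 (-3.29 ± 0.15) on day 10, and Aqp1 (-3.40 ± 0.15), Actg2 (-3.36 ± 0.17) and Prl2c3 (-3.13 ± 0.16) on day 14.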

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

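Gene counts, 2-fold counts, 87 list results and 219 named gene results were computed again under the alternatives fixed beforehand and with single arrays left out, peak day counts only under 4 of the alternatives, and the fit without day 4 replicate 2 was examined further after the result was seen. None of these list or named gene results turned direction; other calls were not followed. Counting each result once per alternative, list results were the same 1423 times and weaker 25 times, and named gene results 3609 and 58 times. Of the gene counts 251 stayed within 1.5 times and 17 moved. With array weights 391 genes passed for day 14 versus day 10, in place of 206. With the replicate block the counts were 2231 for day 8 versus day 6, 1016 for day 10 versus day 8, 573 for day 14 versus day 10 and 99 for day 18 versus day 14. With only the 2 time points compared they were 614, 31, 50 and 2, where the fit has fewer arrays to estimate variance. Leaving out single arrays moved day 10 versus day 8 to 204 (without day 8 replicate 1), 227 (day 8 replicate 2), 240 (day 8 replicate 3) and 185 (day 10 replicate 2), and without day 4 replicate 2 it was 465. It moved day 14 versus day 10 to 112 (without day 14 replicate 3), with 250 without day 4 replicate 2, and day 18 versus day 14 to 26 (day 14 replicate 1), 29 (day 14 replicate 3) and 25 (day 18 replicate 1), with 56 as the highest (day 18 replicate 3). The cause of these moves was not tested. Of the 2-fold counts 216 were the same and 19 moved. Without background correction all 14 were lower, from 1488 to 708 for day 2 versus day 0 and from 453 to 146 for day 6 versus day 4, since background left in both intensities compresses their ratio. With the series matrix values they were 39 for day 10 versus day 8, 42 for day 14 versus day 10 and 23 for day 18 versus day 14. The percent of passing genes that were higher crossed 50% in 4 comparisons. For day 6 versus day 4 (52.2%) it was 47.1% with median centring, 49.2% with the replicate block and 49.9% without day 6 replicate 1. For day 10 versus day 8 (59.8%) it was 49.6% without day 10 replicate 1 and 71.0% with only the 2 time points. For day 14 versus day 10 (52.4%) it was 42.1% with median centring and 68.0% with only the 2 time points. For day 18 versus day 6 (49.3%) it was up to 52.6% with single arrays left out. Median centring gave 32.7% for day 14 versus day 0 (41.5%), and the replicate block 80.8% for day 18 versus day 14 (93.5%). Of the peak day counts 31 were the same and 33 moved. Genes highest on day 0 fell from 1339 to 757 without background correction and 489 with a 4-fold range, and genes lowest on day 0 from 1129 to 745 and 426, as fewer genes span the range required. Median centring moved day 14, from 234 to 125 highest and from 331 to 523 lowest. A block for the chip was not run, since the chip of each sample is not given in the sources used here.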

Other observations

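The 6 lists of this first part were chosen after the data were seen, and every test in the parts below was chosen after its result was seen. The p-values of these 6 lists were adjusted over the 6 alone. They describe the changes and do not serve as an independent test. All 8 apolipoprotein genes rose from day 4 to day 6 (median log2 change 1.64, adjusted p = 4.42e-09), and 7 of them were higher on day 18 than on day 0 (adjusted p = 0.000195). Of 17 peroxisome genes 13 rose from day 2 to day 4 (adjusted p = 4.17e-08), 16 were higher on day 18 than on day 0 (adjusted p = 9.57e-09), and 11 fell and 2 rose from day 6 to day 18 (adjusted p = 0.0164). Of 14 genes of MHC class I antigen presentation 9 fell by day 2 (adjusted p = 0.00337, and adjusted p = 0.0665 with an estimated correlation), 9 rose from day 4 to day 6 (adjusted p = 0.000117), and 12 were higher and 1 lower on day 18 than on day 0 (adjusted p = 0.000195).

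Of 11 imprinted growth genes 8 fell from day 2 to day 4 (adjusted p = 0.0011) and 5 rose from day 6 to day 18 (adjusted p = 0.0164). Of 8 complement genes 5 fell by day 2 (adjusted p = 0.0189, and adjusted p = 0.0665 with an estimated correlation) and 5 rose from day 6 to day 18 (adjusted p = 0.0164). Of 9 keratins and cornified envelope genes 5 rose and 2 fell from day 2 to day 4 (adjusted p = 0.0297, and adjusted p = 0.0554 with an estimated correlation), and 4 fell from day 6 to day 18 (adjusted p = 0.0164).

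Day 4 replicate 2 held late genes above the other day 4 arrays, in a test chosen after this was seen. If RNA of a late time point were in the sample, its genes should stand at one share of their day 18 signal, and over 93 genes the median share was 10.9% (quartiles 9.0% and 12.1%), consistent with such RNA. If the whole culture were further along, genes that fall from day 4 to day 6 should be lower on it. Over 17 genes whose median change was -2.12 the median difference was -0.09 (interquartile range 0.24), which argues against a whole culture in the day 6 state. A small part of the cells further along would lower these genes little and cannot be told apart from added late RNA. The named medium also changed between days 4 and 6, so these genes need not fall with the stage alone. If all arrays of number 2 carried late RNA, those of day 0 and day 2 should hold late genes too. The highest share there was 0%, which argues against this for days 0 and 2. An effect of the replicate number that starts on day 4 cannot be judged from those days. Whether such RNA came from another sample or from cells of this culture was not tested.

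Arrays of replicate number 1 differed from those of numbers 2 and 3 over the days, with a root mean square deviation of 0.188 against 0.139 and 0.102. If this were a difference in transcript level, probes of the same gene should shift together. Over 1712 genes their correlation was 0.12 (0.07 to 0.17) for number 1 minus number 2 and 0.22 (0.15 to 0.29) for number 1 minus number 3. It was 0.92 for day 18 minus day 0 and 0.71 for day 10 minus day 8. By a bound set after the result was seen, this argues against transcript level as the main source. A smaller part at that level is left open. If number 1 were a culture at another stage, its shift should follow the course, and the correlation with the day 18 minus day 0 change was -0.08, which argues against this. A step in labelling, hybridisation or chip should shift single probes, and the other probe of the gene went the same way in 50.5% of large shifts against number 2 (49 of 97) and in 69.3% against number 3 (61 of 88). The share against number 3 lies between the bounds of 65% and 80% used in this test, so such a step is left open, as is the difference between numbers 2 and 3 (probe correlation 0.39, 0.33 to 0.45).

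Scaling of the arrays was examined as a source of the rise of interferon-stimulated, matrix and actin genes from day 6 to day 18. A rise made by the choice of scaling should go away under another scaling. The lowest list median over all scalings was 0.35, with the largest shift of all genes at 0.109. The rise therefore did not depend on which of these scalings was used. All of them bring the arrays to a like level, so an error that they share cannot be seen this way. If a growing share of cells in the day 0 state made the rise, genes lower on day 6 than on day 0 should regain the same part in every list. Against mitosis genes (median 5.2%), interferon-stimulated genes regained 130.1 points more (98.75% interval 80.6 to 345.1), matrix genes 20.2 (7.3 to 45.4) and actin genes 24.3 (5.4 to 45.6). Mitosis genes had risen by day 2, and cells in the day 0 state need not divide, so this comparison alone cannot decide. Against preadipocyte genes (10.8%) the differences were 124.6 (69.4 to 342.2), 14.7 (-5.3 to 45.4) and 18.7 (-6.6 to 41.8). Against basement membrane genes the interval of interferon-stimulated genes lay above 0 (77.9 to 344.8), while those of matrix and actin genes held 0. This argues against such a share as the only source for interferon-stimulated genes. For matrix and actin genes a share of such cells that no longer divide is left open. The intervals resample genes of lists picked for their rise, so they do not measure variation between cultures. The end of dexamethasone and IBMX in the medium is left open. Glucocorticoid targets fell from day 6 to day 18 (median -0.83), but the named medium changed earlier, between days 4 and 6. Over that step, without day 4 replicate 2, 3 of these targets rose and 6 fell, and the list did not pass (adjusted p = 0.182). No day was measured in both media, so medium and time cannot be told apart.

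Random splits of the arrays were made after the counts were seen. The real grouping of arrays by day gave 7125 genes in the F test, which does not use the order of the days. The others of 100 splits gave at most 1884, and at most 2698 when arrays were split within replicate numbers. This argues against a random assignment of arrays to days for the course. Groups that mix days also have a larger spread, which lowers their counts. For single contrasts only 10 splits exist, too few to judge such an assignment. The highest other count was 2 for day 2 versus day 0 and 1 or 0 elsewhere.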
